A study of Homo sapiens with 6 samples.

How the data were processed

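Total RNA of HCT116, an established human colon cancer cell line, was sequenced from cells that stably expressed either wild-type PHF5A (WT) or the K29Q form of PHF5A, in which a glutamine replaces a lysine (K29Q). Each group had 3 libraries, named WT 1 to 3 and K29Q 1 to 3 after their labels. The labels do not say whether the 3 libraries of a group came from separate cultures or separate stable lines. The p-values of the gene test therefore measure only the spread between these libraries, which may be technical, and the list tests build on the same libraries.

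The deposited table gave 1 FPKM value (fragments scaled by transcript length and by the mapped fragments of the library) per gene and library, per the file headers. Reads were aligned to GRCh38 with HISAT2 2.1.0 and quantified with StringTie, per the submitters' processing notes. The StringTie version, the annotation release, the settings and the strand option are not given in the sources used here. The table held 60675 gene IDs with a symbol each, and 0 columns belonged to samples outside the series. Coordinates and gene types were looked up by gene ID in GENCODE 29 on GRCh38, where 57055 of the IDs and 13124 of the tested IDs were found. Gene totals hold no information on splicing or on which codon a PHF5A read carried. The table held gene values only, so transcripts were not tested.

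FPKM values are not counts, and the depth per library is not stated. The values of single-exon genes longer than 600 nt moved in steps, which gave an estimate of what 1 fragment was worth. If 1 step was 1 fragment, the estimated depth ran from 33600000 fragments in K29Q 3 to 40000000 in K29Q 2. FPKM sums ran from 249034 to 253451 per library. StringTie divides fragments among overlapping transcripts, so the steps were not used to recover counts and no count test was run. An FPKM of 0 can also be a failed assignment among overlapping gene models, and a gene is then said to be listed at 0.

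The column headers carried a sequencing run name, read here as the flow cell. Flow cell A held 2 K29Q libraries (1 and 2) and 1 WT library (2), and flow cell B held 1 K29Q library (3) and 2 WT libraries (1 and 3). Differences within each flow cell are therefore given beside the pooled ones. No pair of libraries was a duplicate.

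Before the data were examined, the test, its samples, 30 gene lists, the rule for named genes and most alternatives were fixed. Genes with an FPKM of at least 1 in at least 3 libraries were kept (13261), and log2(FPKM + 1) values of the 6 libraries were fitted with limma 3.58.1 in R 4.3.3 using an intensity trend, with the group as the only term. Every adjusted p for a gene is from this limma test with Benjamini-Hochberg adjustment over the 13261 genes, and the threshold was an adjusted p of 0.05. Fold changes and their SE are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Ratios of mean FPKM are given beside them. Counts adjusted over the list alone use the same p-values with the Benjamini-Hochberg adjustment over the measured members of 1 list.

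Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided. Camera compares the mean test statistic of the members with that of the other genes, and members are then said to score higher or lower. At the preset correlation this difference is set against the spread across genes, so a small p does not measure how well libraries repeat. Benjamini-Hochberg adjustment ran over the 27 lists with at least 5 measured members. The same test with a correlation estimated per list, and fry (limma), which asks whether the members move one way on balance without comparing them with other genes, were run beside it. Of 852 list entries 850 were found in the table by current or older symbol. The lists covered the SF3B complex and U2 snRNP, SR proteins and hnRNPs, transcripts known to be degraded by nonsense-mediated decay (NMD), histone demethylases, HIF1 targets, metabolism, stress and signalling programmes, the cell cycle, histones, interferon-induced genes, epithelial and mesenchymal genes, and markers of enterocytes and goblet cells, of fibroblasts and endothelium, and of leukocytes.

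The rule for named genes took PHF5A and KDM3A, up to 10 genes with the largest fold changes in each direction among those past the threshold (official symbol, mean log2 value of at least 3, groups not overlapping), the 5 with the highest expression among those past the threshold, and up to 4 members with the smallest p from each list. The single members of the mesenchymal list are not reported here. Genes named outside this rule are marked as chosen after their values were seen. For PHF5A and KDM3A an exact two-sided permutation test of the 3 against 3 log2 values was added, whose smallest possible p is 0.1.

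Settings fixed beforehand as alternatives were quantile normalization, no filter on low values, a mean FPKM of at least 5, a pseudocount of 0.1, the replicate number as a block, leaving out each library in turn, and a fold change threshold. Alternatives chosen after seeing the data were a flow cell term, a correction for GC content and length, both of these in combination with other terms, leaving out gene models that overlap another locus, the HIF1 list without KDM3A, and the estimated correlation with a library left out. The GC and length correction subtracted from each library a natural spline (4 degrees of freedom each) on the GC content and log2 length of the longest GENCODE 29 transcript, for the 13108 tested genes with one (98.8%).

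The gene and list tests were tested on simulated data of the real size, with 200 of 13261 genes changed by known folds. They recovered 82% of the genes changed 1.5-fold and 98% of those changed 2-fold, each with the right sign, and 5.26% of the calls were false. With no change simulated 0 genes were called. The list test called 1 list, the shifted one. A GC trend simulated between the groups raised this to 2 lists and the correction brought it back to 1. The simulated genes varied independently, while the correlation estimated in the data was 0.331 for ribosomal proteins and 0.137 for HIF1 targets. The simulation therefore does not show how often correlated genes give false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.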

Results

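The series compared HCT116 colon cancer cells that stably expressed wild-type PHF5A with cells that expressed the K29Q form. PHF5A is a small subunit of SF3B, the part of the U2 snRNP that recognises the intron branch site, and glutamine is commonly used as a mimic of acetylated lysine. The series title links PHF5A acetylation to stress responses and to higher KDM3A by way of splicing, so the comparison asks which genes differ between K29Q and WT cells. Expression was measured as FPKM per gene in 3 WT and 3 K29Q libraries. Between 12916 genes (WT 2) and 13298 genes (K29Q 3) had an FPKM of at least 1. Estimated depths lay between 33600000 and 40000000 fragments.

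PHF5A itself was more abundant in the K29Q cells. Its FPKM was 33.1 ± 1.06 in WT and 44.1 ± 2.38 in K29Q (SD, n = 3 each), a ratio of 1.33, and all 3 K29Q libraries lay above all 3 WT libraries. The gene (ENSG00000100410) lies on chromosome 22 from 41459717 to 41468725 (GRCh38, minus strand) and codes for protein. The log2 fold change was 0.40 (SE 0.064, 95% confidence interval 0.25 to 0.55) and did not pass the threshold over all genes (limma, adjusted p = 0.11). It passed when adjusted over the list alone, among 25 measured SF3B and U2 snRNP genes (Benjamini-Hochberg, adjusted p = 0.0105). The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The log2 difference was 0.34 within flow cell A and 0.46 within flow cell B. After correction for GC content and length it was 0.43 and passed the threshold over all genes (adjusted p = 0.0201), and this call was lost at the same fold change when a flow cell term was added (adjusted p = 0.0805). Gene totals add the endogenous and the introduced PHF5A together and do not tell the mutant from the wild type.

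KDM3A, a JmjC histone H3 lysine 9 demethylase and a known HIF1 target, is named in the series title. Its FPKM was 4.19 ± 0.196 in WT and 5.82 ± 0.678 in K29Q (SD, n = 3 each), a ratio of 1.39, with no overlap between the groups. KDM3A (ENSG00000115548) lies on chromosome 2 from 86440647 to 86492716 (plus strand). The log2 fold change of 0.39 (SE 0.086, 95% confidence interval 0.19 to 0.60) did not pass the threshold over all genes (limma, adjusted p = 0.235), and the exact permutation p was 0.1. It was 0.39 within flow cell A and 0.35 within flow cell B. Adjusted over the list alone, KDM3A passed among 23 measured JmjC and LSD1 demethylases (adjusted p = 0.0327) and among 30 measured HIF1 targets (adjusted p = 0.00866). After correction for GC content and length the log2 fold change was 0.28. JMJD1C, a relative of KDM3A with FPKM of 3.63 ± 0.625 and 5.70 ± 0.670, was the other demethylase past the threshold adjusted over the list alone (adjusted p = 0.0327), at a log2 fold change of 0.54. As a group the demethylases did not pass the list test: 15 members lay above 0 and 8 below, 0 passed over all genes (limma, 5 at an unadjusted p under 0.05), 2 passed adjusted over the list alone, and the camera adjusted p was 0.13.

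**Figure D1:**
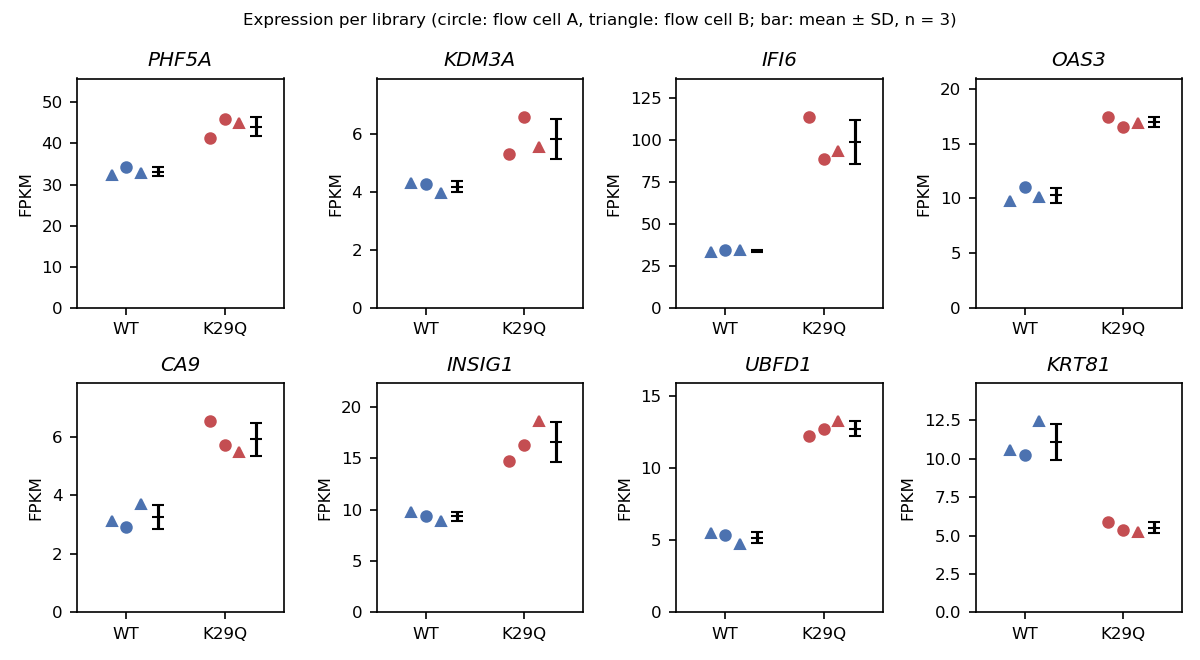
FPKM of 8 genes in each of the 3 WT (blue) and 3 K29Q (red) libraries, with circles for flow cell A, triangles for flow cell B and black bars for the mean ± SD of each group (n = 3). The groups do not overlap in any of the 8 panels, with IFI6 at 34.1 against 98.9, UBFD1 at 5.19 against 12.7 and KRT81 at 11.1 against 5.51 on average.

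Over all genes, 7 of 13261 passed the threshold, 4 higher and 3 lower in K29Q. IFI6, an interferon-induced protein of the inner mitochondrial membrane, rose from 34.1 ± 0.663 to 98.9 ± 13.3 FPKM (SD, n = 3 each), a ratio of 2.90 and a log2 fold change of 1.50 (SE 0.096, limma, adjusted p = 0.00352). UBFD1, a protein with a ubiquitin-like domain, rose from 5.19 ± 0.389 to 12.7 ± 0.498 FPKM, a ratio of 2.45 (log2 fold change 1.15, SE 0.071, adjusted p = 0.00352). OAS3, which makes the 2'-5' oligoadenylate that activates RNase L, rose from 10.3 ± 0.653 to 16.9 ± 0.463 FPKM, a ratio of 1.65 (log2 fold change 0.67, SE 0.066, adjusted p = 0.0357). KRT81, a hair-type keratin, fell from 11.1 ± 1.17 to 5.51 ± 0.347 FPKM, a ratio of 0.497 (log2 fold change −0.89, SE 0.087, adjusted p = 0.0357). IFI6 (ENSG00000126709) lies on chromosome 1 from 27666061 to 27672218, UBFD1 (ENSG00000103353) on chromosome 16 from 23557362 to 23574389, OAS3 (ENSG00000111331) on chromosome 12 from 112938352 to 112973249 and KRT81 (ENSG00000205426) on chromosome 12 from 52285913 to 52291534. Within flow cells A and B the log2 differences were 1.52 and 1.44 for IFI6, 1.08 and 1.22 for UBFD1, 0.58 and 0.71 for OAS3, and −0.763 and −0.996 for KRT81. KRT81 overlaps its near-identical paralog KRT86, so reads may be divided between them, and KRT86 had 1.94 ± 0.345 and 1.05 ± 0.232 FPKM (chosen after its values were seen). OAS3 and KRT81 each lost the call whichever single library was left out (adjusted p from 0.054 to 0.14 for OAS3 and from 0.0522 to 0.139 for KRT81) and with a flow cell term (0.15 for each). With the replicate number as a block OAS3 (0.295), KRT81 (0.233) and UBFD1 (0.0597) lost the call. With no filter on low values, which tests more genes, IFI6 (0.0578), OAS3 (0.124) and KRT81 (0.142) fell short of the threshold.

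The other 3 genes past the threshold were gene models that share a locus or a symbol with another entry. IFI6 or UBFD1 was also annotated as overlapping another locus. RP11-111K18.1 (ENSG00000256646, chromosome 7 from 42909273 to 42932174), a model that runs through C7orf25 and the proteasome gene PSMA2, fell from 10.2 ± 1.14 to 2.48 ± 0.303 FPKM (log2 fold change −1.68, SE 0.103, limma, adjusted p = 0.00352), at −1.68 within flow cell A and −1.80 within flow cell B. PSMA2 had 17.6 ± 0.451 FPKM in WT and 21.8 ± 0.476 in K29Q. RP13-1032I1.10 (ENSG00000262660, chromosome 17 from 81703371 to 81720539), which overlaps MRPL12 and SLC25A10, had 3.54, 3.39 and 3.45 FPKM in WT 1 to 3 and was listed at 0 in all 3 K29Q libraries (adjusted p = 7.15e-05). A second entry for ATRIP, the partner of the DNA damage kinase ATR (ENSG00000282827, with no position in the annotation used here), rose from 0.223 ± 0.135 to 1.71 ± 0.111 FPKM (adjusted p = 0.0184), with log2 differences of 1.26 and 1.06 within flow cells A and B. The first ATRIP entry (ENSG00000164053, chromosome 3 from 48446710 to 48467645) had 5.19 ± 0.523 and 1.65 ± 0.432 FPKM and did not pass (adjusted p = 0.0502), though it did with quantile normalization (0.0411), without K29Q 1 (0.0356) and after GC and length correction (0.0397), and the sum of both entries was 5.42 ± 0.513 and 3.36 ± 0.331. PSMA2, RP13-1032I1.10 and both ATRIP entries were chosen after their values were seen. The second ATRIP entry lost the call without WT 2 (adjusted p = 0.0905), K29Q 1 (0.0522), K29Q 2 (0.106) or K29Q 3 (0.0555). It also lost it with a flow cell term (0.0884), with the replicate block (0.105) and with a pseudocount of 0.1 (0.0715). With no filter on low values RP11-111K18.1 (0.0567) and the second ATRIP entry (0.142) fell short of the threshold.

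Beyond these 7 genes small differences were spread over the transcriptome, some of them along lines other than the groups. An unadjusted p under 0.05 was reached by 1664 genes, of which 1015 were higher and 649 lower in K29Q. The split that set WT 1, K29Q 2 and K29Q 3 against the other libraries reached 1536 genes, and the one with WT 1, K29Q 1 and K29Q 3 reached 1096. The groups did not overlap for 2361 genes (17.8%, where chance gives 10%). WT 1 lay beside the K29Q libraries on the first principal component (34.1% of the variance), at −4.72 against 13.22 and 17.99 for WT 2 and WT 3 and −4.76 to −14.92 for K29Q. Without WT 1 the test called 20 genes (17 higher, 3 lower), and without K29Q 1 it called 12 (4 higher, 8 lower). Fold changes also followed GC content: the median log2 fold change was 0.15 for genes whose longest transcript had a GC content of up to 40% and −0.05 for those over 60%, with a Pearson correlation across genes of −0.364 (genes are not independent replicates). The slope per 10% of GC content, relative to the mean of the 6 libraries, was −0.043, 0.026 and 0.118 in WT 1 to 3. In K29Q 1 to 3 it was 0.022, −0.056 and −0.068, so WT 3 was highest and the slopes overlapped between the groups. After each library's trend on GC content and length was subtracted, the medians of the GC classes lay between −0.01 and 0.01, and 83 genes passed the threshold (61 higher, 22 lower), 6 of them among the 7 above. With a flow cell term added to the correction 5 genes passed (2 higher, 3 lower). The 83 included 10 interferon, 5 HIF1 and 4 cholesterol list members.

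**Figure D2:**
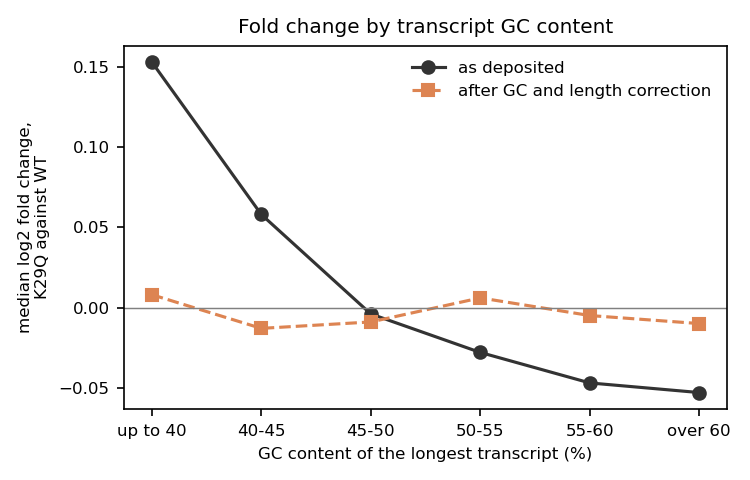
Median log2 fold change (K29Q against WT, on log2(FPKM + 1)) of the tested genes in 6 classes of GC content of the longest transcript, as deposited (black) and after subtracting each library's trend on GC content and length (orange). The deposited values run from 0.153 in the class up to 40% to −0.053 in the class over 60%, and the corrected ones from −0.013 to 0.008. The GC slopes of single libraries overlapped between the groups.

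Of the 27 gene lists tested, 8 passed the camera test, 5 higher and 3 lower in K29Q. The interferon-induced genes, which include sensors of foreign RNA and antiviral effectors, rose together. Of 26 measured members 23 lay above 0 and 3 below, with a median log2 fold change of 0.42 (camera adjusted p = 4.03e-15). Over all genes 2 members passed (IFI6 and OAS3), and 15 passed, all higher, when adjusted over the list alone. OAS1 went from 0.397 ± 0.0598 to 1.25 ± 0.0587 FPKM (ratio 3.15), and IFIH1, the double-stranded RNA sensor MDA5, from 1.51 ± 0.245 to 3.31 ± 0.140 FPKM (ratio 2.19), each with an adjusted p of 0.000246 adjusted over the list alone. These 2 did not pass over all genes (0.0502 and 0.0571). The list passed with an estimated correlation (adjusted p = 0.0206) and under fry (0.000237). Its median was 0.45 within flow cell A and 0.45 within flow cell B, and 0.40 after GC and length correction. With an estimated correlation the call was lost whichever library was left out (adjusted p from 0.0635 without WT 2 to 0.186 without WT 1). Each of these fits also had fewer libraries, so the loss does not show that the call rested on a single library.

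Genes of sterol synthesis and its control also rose as a group. Of 24 measured members 20 lay above 0 and 4 below, with a median log2 fold change of 0.22 (camera adjusted p = 5.67e-09). Over all genes 0 passed (limma, 15 at an unadjusted p under 0.05), and 12 passed, all higher, when adjusted over the list alone. INSIG1, the sterol-responsive anchor of the SREBP processing complex, went from 9.34 ± 0.439 to 16.6 ± 1.94 FPKM (ratio 1.77, adjusted p = 0.0017 adjusted over the list alone). HMGCS1, which makes HMG-CoA, went from 15.9 ± 1.59 to 24.7 ± 1.67 FPKM (ratio 1.55, 0.00282), and lanosterol synthase LSS from 17.1 ± 1.17 to 22.3 ± 0.546 FPKM (ratio 1.30, 0.00771). The list passed with an estimated correlation (adjusted p = 0.0319) and under fry (0.000511). Its median was 0.25 within flow cell A and 0.17 within flow cell B, and 0.23 after GC and length correction. With an estimated correlation the call was lost whichever library was left out (adjusted p from 0.0667 without WT 3 to 0.191 without WT 1), and after GC and length correction it was lost at 0.118. The fits with a library left out also had fewer libraries, so their loss does not show reliance on a single library.

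HIF1 and hypoxia targets, to which KDM3A belongs, were the third group that rose. Of 30 measured members 27 lay above 0 and 3 below, with a median log2 fold change of 0.23 (camera adjusted p = 3.7e-13), and this call was lost with an estimated correlation (adjusted p = 0.16). Over all genes 0 passed (limma, 15 at an unadjusted p under 0.05), and 15 passed, all higher, when adjusted over the list alone. CA9, a cell-surface carbonic anhydrase, went from 3.24 ± 0.411 to 5.90 ± 0.553 FPKM (ratio 1.82), FAM162A from 11.3 ± 0.344 to 15.9 ± 0.794 (ratio 1.41) and the aldolase ALDOC from 22.0 ± 0.559 to 32.1 ± 2.92 (ratio 1.46), each with an adjusted p of 0.00254 adjusted over the list alone. P4HA1, a collagen prolyl hydroxylase, went from 19.7 ± 2.09 to 29.4 ± 1.73 FPKM (ratio 1.495, 0.00309). The list passed under fry (0.00804). Its median was 0.21 within flow cell A and 0.30 within flow cell B, and 0.17 after GC and length correction. Glycolysis, which shares ALDOC and other genes with this list, did not pass: 12 of 20 members lay above 0, 0 passed over all genes, 1 (ALDOC) passed adjusted over the list alone, and the camera adjusted p was 0.227. The glycolysis list passed after GC and length correction (0.0131) and with quantile normalization (0.00824). With an estimated correlation its adjusted p was 0.652, and 0.51 after GC and length correction.

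**Figure D3:**
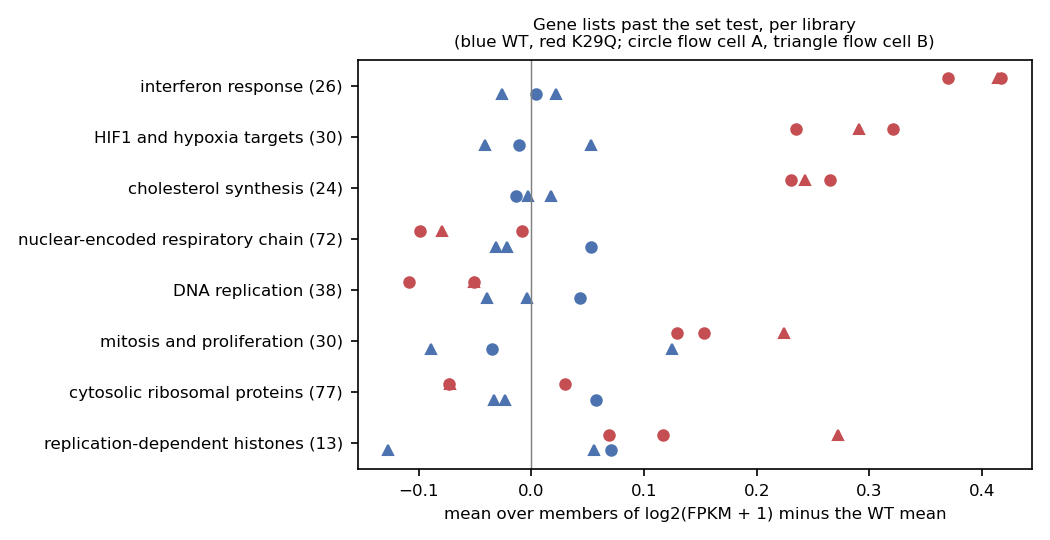
Mean over the members of each of the 8 gene lists past the camera test of log2(FPKM + 1) minus the WT mean, per library, with WT in blue, K29Q in red, circles for flow cell A and triangles for flow cell B, and the number of measured members in brackets. The K29Q libraries lie at 0.37 to 0.42 for interferon genes, 0.24 to 0.32 for HIF1 targets and 0.23 to 0.27 for cholesterol synthesis, all above the WT libraries. The groups overlap for the respiratory chain, ribosomal proteins and histones.

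The cell cycle and histone lists passed camera at its preset correlation alone. Mitosis genes scored higher than other genes, with 21 of 30 members above 0 and a median log2 fold change of 0.19 (camera adjusted p = 0.01, adjusted p = 0.41 with an estimated correlation, and 0.274 under fry). Relative to the WT mean, mitosis genes averaged 0.125 in WT 1, close to K29Q 1 and 2 (0.153 and 0.129), and −0.035 and −0.089 in WT 2 and WT 3. ASPM, which acts at spindle poles, had 6.31 ± 1.56 and 10.3 ± 1.56 FPKM (ratio 1.64), and topoisomerase TOP2A 28.0 ± 6.33 and 39.0 ± 3.72 (ratio 1.40). DNA replication genes scored lower, with 34 of 38 members below 0 and a median of −0.09 (camera adjusted p = 0.00122, adjusted p = 0.41 with an estimated correlation, and 0.23 under fry). The licensing factor CDT1 had 36.5 ± 3.02 and 30.2 ± 3.19 FPKM, and GINS1 12.9 ± 0.604 and 11.2 ± 0.820, while RFC1 had 9.02 ± 1.06 and 11.3 ± 0.757. Of both lists 0 members passed, over all genes or adjusted over the list alone (limma, 10 mitosis and 7 replication genes at an unadjusted p under 0.05). Histone genes scored higher, with 11 of 13 members above 0 and a median of 0.17 (camera adjusted p = 0.0471, adjusted p = 0.41 with an estimated correlation, and 0.234 under fry). Over all genes 0 histone genes passed, and 2 passed adjusted over the list alone: HIST1H2BD with 19.9 ± 0.942 and 26.9 ± 1.70 FPKM (adjusted p = 0.00852) and the linker histone HIST1H1C with 26.4 ± 2.80 and 33.3 ± 1.26 (0.0374). Within flow cells A and B the medians were 0.14 and 0.25 for mitosis, −0.13 and −0.06 for DNA replication, and 0.04 and 0.30 for histones. The histone call was lost without WT 1 (adjusted p = 0.124), WT 3 (0.195) or K29Q 3 (0.194), and the mitosis call without WT 3 (0.195). With no filter on low values the histone list fell short (0.0519), and with overlapping gene models left out as well (0.18).

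The respiratory chain and ribosomal protein lists also passed camera at its preset correlation alone, and their mean values per library overlapped between the groups. Nuclear-encoded respiratory chain genes scored lower than other genes, with 58 of 72 members below 0 and a median log2 fold change of −0.06 (camera adjusted p = 0.000739, adjusted p = 0.458 with an estimated correlation, and 0.293 under fry). NDUFB9, a subunit of complex I, had 38.5 ± 6.10 and 28.6 ± 0.802 FPKM. Cytosolic ribosomal protein genes scored lower, with 59 of 77 members below 0 and a median of −0.04 (camera adjusted p = 0.0103, adjusted p = 0.652 with an estimated correlation, and 0.518 under fry). RPL23 had 70.7 ± 3.57 and 59.0 ± 3.996 FPKM. Of both lists 0 members passed, over all genes or adjusted over the list alone (limma, 5 respiratory chain and 4 ribosomal protein genes at an unadjusted p under 0.05). Within flow cells A and B the medians were −0.11 and −0.04 for the respiratory chain and −0.09 and −0.04 for ribosomal proteins. The ribosomal protein call was lost after GC and length correction (adjusted p = 0.248), kept with a flow cell term added to the correction (0.0271), turned to higher with quantile normalization (0.46), and was lost without WT 2 (0.391), K29Q 1 (0.183) or K29Q 3 (0.194) and at a mean FPKM of at least 5 (0.125). The respiratory chain call was lost without WT 2 (0.093) and with quantile normalization (0.209). The 13 mitochondrially encoded genes did not pass (camera adjusted p = 0.451).

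The groups closest to PHF5A's own function did not pass the list test. Of 25 SF3B and U2 snRNP genes 8 lay above 0 and 17 below (camera adjusted p = 0.227), and PHF5A was the single member past the threshold adjusted over the list alone. SF3B1, the largest subunit of the complex, had 31.3 ± 4.84 and 36.7 ± 0.154 FPKM. Of 35 SR proteins and hnRNPs 23 lay above 0 and 12 below (camera adjusted p = 0.227), and 0 passed either way (limma, 4 at an unadjusted p under 0.05). The splicing kinase CLK1 had 3.42 ± 0.409 and 4.64 ± 0.395 FPKM. Transcripts known to be degraded by NMD had 18 of 25 members below 0 (camera adjusted p = 0.0784) with 0 past either threshold (5 at an unadjusted p under 0.05), and this list was called lower by fry (adjusted p = 0.0013) and by camera with no filter on low values (0.0332), against an adjusted p of 0.402 from camera with an estimated correlation. SMG1, the kinase that starts NMD, had 7.47 ± 1.26 and 9.67 ± 0.589 FPKM. The SR protein and hnRNP list passed as higher with quantile normalization (0.0157) and turned to lower after GC and length correction (0.248). With an estimated correlation its adjusted p was 0.672 as deposited and 0.623 after GC and length correction.

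Stress, signalling and differentiation lists did not pass either. Among ATF4 targets (35 measured, camera adjusted p = 0.107) 0 passed over all genes and 2 adjusted over the list alone. The amino acid transporter SLC38A2 had 54.0 ± 9.78 FPKM in WT and 91.1 ± 4.80 in K29Q (ratio 1.69, 0.016), and the pseudokinase TRIB3 11.2 ± 0.548 and 7.10 ± 1.58 (ratio 0.637, 0.0493). Among WNT targets (17, camera adjusted p = 0.085) cyclin D1, CCND1, had 171 ± 3.10 and 134 ± 1.58 FPKM (ratio 0.784, 0.00411), and among AP-1 and immediate early genes (23, camera adjusted p = 0.227) FOSL1 had 42.1 ± 3.02 and 27.0 ± 4.30 (ratio 0.640, 0.0207). Each of these 2 was the single member past the threshold adjusted over the list alone, and 0 passed over all genes. The WNT list passed as lower without WT 1 (0.0425), and with all libraries its adjusted p was 0.458 with an estimated correlation. The same count was 2 for NRF2 targets (ABCC2 higher, FTH1 lower, 0.666), 1 for NF-kB genes (NFKBIA higher, 0.777) and 1 for epithelial genes (ELF3 higher, 0.085), with 0 over all genes in each. The mesenchymal list did not pass (14 measured, camera adjusted p = 0.227), with 4 members past the threshold adjusted over the list alone (1 higher, 3 lower) and 0 over all genes. In 6 lists 0 members passed either way: p53 targets (camera adjusted p = 0.227, 2 members at an unadjusted p under 0.05), MYC targets in ribosome biogenesis (0.227, 3 members), autophagy and lysosome genes (0.203, 0 members), endoplasmic reticulum chaperones (0.609, 3 members), cytosolic heat shock proteins (0.884, 1 member) and metallothioneins (0.558, 1 member). For the 2 chaperone lists the mean log2 fold change was positive (0.01 and 0.04) while the median was negative (−0.02 and −0.02).

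Few markers of other cell types reached the filter on low values. Of the leukocyte markers 1 was measured (CD68, at most 2.0 FPKM) and of the fibroblast and endothelial markers 1 (COL1A1, at most 5.93 FPKM). Of the enterocyte and goblet cell markers 4 were measured, the highest being CA2 at 9.67 FPKM, and all 4 had log2 fold changes below 0, 2 of them at an unadjusted p under 0.05 and 0 past the threshold (limma), over all genes or adjusted over the list alone. These 3 lists had too few measured members for the list test.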

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

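The flow cell term, the GC and length correction and its combinations, overlapping gene models left out, fry with the block, and the estimated correlation in combination were chosen after the results were seen. The number of genes past the threshold (7) was 13 with quantile normalization (9 higher, 4 lower), 2 with no filter on low values (2955 at an unadjusted p under 0.05), 4 with the flow cell term, 83 after GC and length correction (5 with the flow cell term added to it) and 4 with overlapping models left out. What caused these differences was not tested. With no filter more genes were tested and the intensity trend was also refitted, and these were not separated. Leaving out each library gave 5 to 20 genes, 6 to 8 lists, PHF5A log2 fold changes of 0.37 to 0.45 and KDM3A ones of 0.31 to 0.45. PHF5A passed after GC and length correction (0.43), but not with the flow cell term (adjusted p = 0.0805) or the replicate block (0.136) added to it. KDM3A kept its direction and stayed short of the threshold over all genes in every alternative run, with log2 fold changes of 0.24 (GC and length correction with the flow cell term) to 0.46 (pseudocount 0.1). Against 8 lists called (5 higher, 3 lower), quantile normalization called 7 higher and 1 lower, and GC and length correction 6 higher and 2 lower. Fry called 4 lists, 3 of them among the 8, and an estimated correlation 2, or 1 after GC and length correction. Deviations from the group mean correlated at −0.14, 0.179 and −0.165 between same-numbered libraries, and at −0.115 to 0.247 between differently numbered ones. With 3 libraries per group this gives no sign of pairing but cannot exclude it. With the replicate block 3 genes passed (1321 at an unadjusted p under 0.05), 1 after GC and length correction with it. UBFD1 kept its fold change with an adjusted p of 0.0597 with the replicate block, and 0.0698 with the correction and the block. With the replicate block fry and the estimated correlation called 0 lists each (6 and 3 at an unadjusted p under 0.05, while camera called 8). The block also takes up degrees of freedom, and the loss of calls was not separated from this. HIF1 targets stayed past the camera threshold at the preset correlation without KDM3A. With KDM3A kept, their adjusted p was 0.16 with an estimated correlation, and 0.479 with the replicate block as well.

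List directions that turned are given by adjusted p, none past the threshold. With quantile normalization these were ribosomal proteins (0.46), heat shock proteins (0.46), endoplasmic reticulum chaperones (0.762) and NRF2 targets (0.762). With no filter they were NF-kB genes (0.96) and NRF2 targets (0.924). At a mean FPKM of 5 they were endoplasmic reticulum chaperones (0.809), heat shock proteins (0.973) and NRF2 targets (0.803). SR proteins and hnRNPs turned after GC and length correction alone (0.248) and combined with the block (0.269), the flow cell term (0.206) or an estimated correlation (0.623). Heat shock proteins turned with the flow cell term (0.922), after correction with the block (0.954) or the flow cell term (0.804), and under fry with the block (0.815). Metallothioneins turned with the flow cell term (0.922) and NRF2 targets with overlapping models left out (0.757). With 1 library left out the direction turned at least once for heat shock proteins (adjusted p over the 6 from 0.65 to 0.984), NF-kB genes (0.434 to 0.781), NRF2 targets (0.373 to 0.989), mitochondrially encoded genes (0.279 to 0.956) and metallothioneins (0.207 to 0.855). The causes were not tested. Depth is only estimated, so the precision of low values is unknown.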

Other observations

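The tests of gene families, the GC and length correction, the flow cell values, the tests of overlapping gene models with and without the genes past the threshold, and the tests of values switching between 0 and at least 1 FPKM and of gene counts over other splits were chosen only after the results were seen. Genes were grouped by name after their values were seen, so their p-values describe these data and are not independent evidence. Of the keratins, KRT8, KRT18, KRT19, KRT23 and KRT80 also belong to the fixed epithelial list, which did not pass (camera adjusted p = 0.085). Keratins, KRT81 among them, were lower in K29Q: 11 of 12 measured members lay below 0 with a median log2 fold change of −0.21 (camera p = 5.6e-07, and p = 0.00662 with an estimated correlation). KRT7 had 19.6 ± 1.73 FPKM in WT and 12.95 ± 0.910 in K29Q (SD, n = 3 each). All 5 measured kallikreins, serine proteases encoded side by side on chromosome 19, lay below 0 with a median of −0.41 (camera p = 1.17e-07, and p = 0.0203 with an estimated correlation). KLK6 had 20.2 ± 0.769 and 14.98 ± 0.429 FPKM and KLK7 10.7 ± 0.348 and 7.65 ± 0.2995. The 3 measured keratin-associated proteins also lay below 0, with KRTAP3-1 at 7.79 ± 0.749 and 3.95 ± 0.566 FPKM. After GC and length correction the medians were −0.16 for keratins and −0.35 for kallikreins, and with quantile normalization −0.23 and −0.44.

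Interferon-induced genes outside the fixed list were chosen from general knowledge after the list result was seen. All 11 measured lay above 0, with a median log2 fold change of 0.28 (camera p = 2.65e-07, and p = 0.00775 with an estimated correlation). The antiviral gene SAMD9 had 1.22 ± 0.302 and 2.85 ± 0.387 FPKM, and the neighbours DTX3L and PARP9, which share a promoter region, had 3.598 ± 0.260 and 6.00 ± 0.466, and 1.74 ± 0.177 and 2.95 ± 0.148. These 3 were left out of the 11 since they had been seen first. Zinc finger genes named ZNF were a large group with a small shift, 162 of 248 above 0 with a median of 0.06 (camera p = 0.000151, but p = 0.123 with an estimated correlation). After GC and length correction their median was 0.03 (camera p = 0.00177, and p = 0.00452 with an estimated correlation).

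The higher interferon, HIF1 and cholesterol lists were weighed against technical causes. After GC and length correction the highest camera adjusted p of the 3 was 4.13e-13, and over the 6 left-out libraries it was 3.05e-05. The lowest median log2 difference within a flow cell was 0.169. At the preset correlation these values argue against a GC or length trend, 1 library or the flow cell as the whole source. Camera p-values were far smaller at the preset correlation than with an estimated one. With the latter the adjusted p was 0.0206 for interferon genes, 0.0319 for cholesterol synthesis and 0.16 for HIF1 targets, which did not pass. The correlation itself was estimated at −0.022, −0.014 and 0.137. For interferon and cholesterol genes it lay below the preset 0.01, so its size does not account for their larger p-values. What else differs between these settings was not examined. After GC and length correction the adjusted p with an estimated correlation was 0.0127 for interferon genes, 0.118 for cholesterol synthesis and 0.147 for HIF1 targets. With 1 library left out, as deposited, camera with an estimated correlation called none of the 3 lists (adjusted p from 0.0635 to 0.529). Since these fits had fewer libraries, this does not tell dependence on a library from lost precision. The K29Q form may raise these programmes, but the libraries may come from 1 stable line per group, and a difference between lines or in PHF5A amount was not tested and stays open.

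The 5 weaker lists were weighed against the GC and length trend alone. After correction the camera adjusted p was 0.00856 for mitosis, 0.000513 for DNA replication, 0.0037 for histones and 0.00384 for the respiratory chain, which argues against that trend as their whole source. The median log2 fold change of mitosis genes fell from 0.19 to 0.117. The corrected medians were −0.089 for DNA replication, 0.179 for histones and −0.061 for the respiratory chain, close to the uncorrected ones. For ribosomal proteins the camera adjusted p was 0.248, with the median log2 fold change going from −0.04 to −0.02. With a flow cell term added to the correction the adjusted p was 0.0271, so whether the trend accounts for that call stays open. A response to K29Q, such as a different growth state of the cells, stays open for all 5, untested and with no call under an estimated correlation.

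Of the 7 genes past the threshold, 3 were annotated as overlapping another locus, each with an absolute log2 fold change of at least 1. The second ATRIP entry is not in that annotation, so these 3 include IFI6 or UBFD1. With such models left out 4 of the 7 still passed, 3 higher and 1 lower. Those 4 include the second ATRIP entry, and KRT81, which lacks the annotation though it overlaps KRT86. Leaving out annotated models therefore does not clear KRT81 or ATRIP of divided reads. Without those 7, 8 of 20 genes with an absolute log2 fold change of at least 1 (40%) had that annotation, against 23.2% of the others (Fisher's exact test, two-sided, p = 0.106, odds ratio 2.2), which does not decide whether reads were divided between overlapping models. With the 7 included it was 11 of 25 (44%, Fisher's exact test, two-sided, p = 0.029), a set holding the genes that prompted the test, and over the 9 other splits of the libraries the share ran from 17.6% to 59.1%, above 44% in 2. Genes listed at 0 in 3 libraries and at 1 FPKM or more in the other 3 also appeared in 4 of the 9 other splits, so the 0 values of RP13-1032I1.10 may come from how reads were assigned. A change in read-through or splicing between the groups stays open, since transcript values were not analysed here.

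The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7 genes and the highest other 7, with 2 splits reaching that count, the real one included. That other split put WT 1 with K29Q 1 and K29Q 3. The split by flow cell gave 3 genes and 7 lists. For lists the real split gave 8 and the highest other 7, and for genes after GC and length correction 83 and 8, so 1 split, the real one, reached the count in each. That 83 was 5 with a flow cell term added to the correction.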
